A study of Mycolicibacterium smegmatis with 16 samples.

How the data were processed

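Ribosome footprints and messenger RNA were sequenced from 2 strains of Mycolicibacterium smegmatis mc2 155 whose small-subunit protein S18 (RpsR) was tagged at its own loci. Per the labels, StrainA carries Flag on the alternative S18 and HA on the canonical S18, and StrainB carries the tags the other way round. Both were grown in Sauton medium with 10 µM ZnSO4 to an OD600 of 1, stopped with 100 µg/ml chloramphenicol for 3 min, and lysed in the frozen state. The lysate was treated with MNase at 70 U/ml and pelleted through 1 M sucrose, and the pelleted ribosomes were digested again and passed over a resin for the tag on the alternative S18. Ribosomes released by tag peptide are called AltRibo here, the flow-through CanRibo, and ribosomes that were not selected TotalRibo, and footprints of 24 to 36 nt were cut from a gel in each case. Per the labels, ribosomal RNA was depleted with a kit in the mRNA libraries and with biotinylated oligonucleotides in the footprint libraries. The series holds 16 samples in 8 groups of 2. The 12 footprint libraries in 6 groups have counts, and the 4 mRNA samples enter only through the translation efficiencies. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

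Footprint counts per gene were deposited by the authors as whole numbers, 1 column per library, in 4 tables that each hold 1 pool and the TotalRibo libraries of 1 strain. The count columns are headed by replicate number and a suffix only, without a pool, so the pool of each was inferred: the columns with identical counts in both tables of a strain were taken as TotalRibo, which the labels place in both, and the others as the first pool in the table's name. The log2 fold changes and mean log2 CPM in the same tables are the authors' own edgeR output, per the file headers, and so are the p-values and false discovery rates. Translation efficiency (TE) was deposited as a ratio of footprint to mRNA level, with 1 value per gene, pool and strain and without a header. FastQC and Bowtie2 are named in the submitters' processing notes, but their versions, the genome build, the program that counted reads, the low-count filter behind the tables and the way replicates were joined in the TE values are not given in the sources used here. Whether counting used the strand or shared reads between copies is not given either, so genes of near-identical copies (the rRNA genes, and a duplicated chromosome segment that includes both serB loci) and overlapping genes are uncertain. The columns so taken as TotalRibo differed between both tables of a strain for 0 of 5995 shared genes in StrainA and 0 of 6173 in StrainB. The order of the strains in the TE columns was taken from the table's name and checked against the counts: the log2 ratio of a pool's TE to the TotalRibo TE correlated with that strain's own fold changes at 0.958 to 0.987 over genes, and with the other strain's at 0.24 or below.

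The 4 tables list 6058, 6035, 6210 and 6251 gene identifiers (StrainA AltRibo, StrainA CanRibo, StrainB AltRibo, StrainB CanRibo), of which 5934, 5912, 6081 and 6113 matched the RefSeq gene table of assembly ASM1500v1. That table was used for names, gene types and the order of neighbours only. No coordinates are given because the authors' build is not known, and the planned checks of gene length and GC content, and the length correction of the gene lists, were not run for the same reason. Identifiers without a match are printed as deposited, with no statement on what they encode.

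Depth ran from 4024722 footprints (StrainB CanRibo replicate 2) to 31999290 (StrainA AltRibo replicate 2). A count of 0 in a library allows a level of up to 0.0938 to 0.745 CPM (here counts scaled to the library total), taking 3 counts as the limit, for counting error only. Gene levels in CPM in the Results are not plain counts over these totals, so they compare with this limit only roughly. The most abundant gene took 1.18% to 6.07% of a library. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 10.1 to 46.8 over genes with at least 20 counts, and no pair of libraries agreed within it (lowest 5.57), so each library was counted as 1 replicate. On a principal component analysis of 5950 genes the first component, with 60.3% of the variance, parted the strains.

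Counts were analysed with R 4.3.3, edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test), limma 3.58.1 for gene lists and DESeq2 1.42.0 as the other tool, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. A gene was called at a Benjamini-Hochberg adjusted p (FDR) below 0.05. AltRibo and CanRibo were each set against TotalRibo within a strain, in a fit of the 4 libraries of that table, which kept 6058, 5943, 5934 and 5819 genes for AltRibo in StrainA and StrainB and CanRibo in StrainA and StrainB. AltRibo was set against CanRibo over both strains with strain as a covariate (8 libraries), and the difference between strains was the interaction of pool and strain. Overlap of calls was tested with a one-sided Fisher's exact test per direction. TE has no replicates, so its values carry no test, SD or interaction model. Zero TE values were left out of log2 ratios, and ratios of AltRibo to CanRibo TE were centred on their median within a strain.

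These groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named the 5 genes of the alternative ribosomal protein operon and the 5 canonical paralogs in every comparison, and the 10 genes highest and 10 lowest among those called in both strains against TotalRibo or, with fewer than 5 such genes in a direction, the 5 with the largest fold change called in each strain. For AltRibo against CanRibo it named the 10 with the smallest p in each direction, and for TE the 5 highest and 5 lowest ratios among 2931 genes above the median footprint level. Genes for rRNA and tRNA were counted, not named. From each gene list it named members called in both strains; no gene was, so list members named here were chosen after their values were seen, by the smallest FDR in each direction. Of 24 lists, 19 were carried over, with their members rewritten as symbols and locus tags because the reference table holds no product names, before any value of a list was read: the alternative operon, canonical paralogs, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ATP synthase, NADH dehydrogenase, cytochromes, iron, zinc, DosR and hypoxia, ESX secretion, fatty and mycolic acid synthesis, TCA cycle, chaperones and proteases, amino acid synthesis, nucleotide synthesis, RNA polymerase and sigma factors, and rRNA with tRNA. The other 5 (PE/PPE, mce, MmpL, ABC transporters and TetR regulators) had no members that could be named and were not analysed here. Lists of at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry. The 87 planned list tests were adjusted together.

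Replicate numbers are shared by the groups in the labels. Same-numbered libraries deviated together from their group means, with correlations over genes of 0.219 (AltRibo and TotalRibo), 0.137 (CanRibo and TotalRibo) and 0.192 (AltRibo and CanRibo) in StrainA and of 0.451, 0.450 and 0.447 in StrainB, and 9 of 12 libraries correlated best with their own number. With 2 libraries per group the deviations of a group are mirror images, so each value rests on 1 contrast per group. The numbers were taken to pair the libraries within a strain, from the data and not from a statement in the labels, and the blocked counts were already known when this was decided. Fits with the replicate number as a block leave 1 residual degree of freedom within a strain, and their values stand beside a result where they change it.

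The tests were tried on simulated counts with the real means and library sizes and 200 changed genes. Each simulation took its spread between libraries (dispersion) from a fit with the design being tried. At 1.5-fold, 2-fold and 4-fold, AltRibo against TotalRibo in StrainA (6057 genes) recovered 59.7%, 80.6% and 100% of changed genes with 5.88% false calls, and in StrainB (5903 genes) 4.48%, 58.2% and 98.5% with 5.31%. CanRibo against TotalRibo recovered 55.2%, 86.6% and 98.5% in StrainA (5894 genes, 3.61% false) and 0%, 28.4% and 86.4% in StrainB (5810 genes, 2.56% false). AltRibo against CanRibo recovered 52.2%, 91.0% and 100% (5930 genes, 2.41% false). With the block, in counts simulated with the real difference between replicate numbers, 1.5-fold changes were recovered at 65.7% and 68.7% for AltRibo in StrainA and StrainB, 73.1% and 47.8% for CanRibo, and 70.1% for AltRibo against CanRibo, with 0.730% to 7.07% false calls. Alternatives were another scaling, no filter, only genes of at least 5 log2 CPM, DESeq2, an FDR of 0.01, an absolute log2 fold change of at least 1, the replicate block, each library left out in turn, rRNA and tRNA genes left out, each strain alone, pseudocounts of 0.1 and 0.01 for TE, and centring. DESeq2, the stricter thresholds and the removal of rRNA and tRNA genes for AltRibo against CanRibo and for the strain difference, the block in the gene lists and in the strain difference, thinned libraries, and the comparison of TotalRibo between strains with its own alternatives were chosen after seeing the data.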

Results

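Ribosome footprints were compared between ribosomes selected by a tag on the alternative form of the small-subunit protein S18 and ribosomes that this selection left behind, in Mycolicibacterium smegmatis mc2 155, a fast-growing mycobacterium used as a laboratory model. Mycobacteria encode zinc-binding (canonical) forms of several ribosomal proteins and, in a zinc-responsive operon, alternative paralogs that lack the zinc-binding residues. The question posed by the design is whether the 2 kinds of ribosome translate different sets of messages. AltRibo denotes ribosomes eluted by way of the tag on the alternative S18, CanRibo the flow-through of the same resin, and TotalRibo ribosomes that were not selected. These names follow the labels, and no value here measures the S18 protein in a pool. Each pool was profiled in 2 strains with swapped tags, StrainA (Flag on the alternative S18, HA on the canonical S18) and StrainB (the reverse), with 2 libraries per pool and strain. AltRibo libraries held 20523630 and 31999290 footprints in StrainA and 9510029 and 7071721 in StrainB. CanRibo libraries held 5293194 and 8229773 in StrainA and 4641385 and 4024722 in StrainB, and TotalRibo libraries 8173171 and 7013592 in StrainA and 4591005 and 4391663 in StrainB. Transfer RNA genes took 2.74% and 2.92% of the StrainA AltRibo libraries against 5.42% to 6.75% of the other StrainA libraries, and 1.08% to 2.72% of the StrainB libraries. Ribosomal RNA genes took 2.80% and 2.69% of the StrainA AltRibo libraries and between 7.11% and 13.8% of the other libraries. Fold changes are log2 ratios from edgeR, n = 2 libraries per group. Their standard error was derived as the absolute fold change over the square root of the F statistic of the quasi-likelihood test. A gene is called higher or lower at an edgeR adjusted p below 0.05.

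Both S18 genes were read first, because the selection rests on them. The tagged alternative rpsR (MSMEG_6065) was translated in StrainA at 98.9 ± 0.871 CPM in TotalRibo (SD, n = 2) and hardly in StrainB, at 1.88 ± 0.353 CPM from 11 and 8 footprints. Its operon neighbour rpsN (MSMEG_6066), the alternative S14, stood at 76.2 ± 12.3 CPM in StrainA and 0.995 ± 0.0363 CPM in StrainB. The canonical rpsR (MSMEG_6895) stood at 346 ± 17.6 CPM in StrainA and 174 ± 42.9 CPM in StrainB. In edgeR the TotalRibo difference of StrainA over StrainB was 5.68 ± 0.19 for the alternative rpsR (adjusted p = 9.13e-05), 6.21 ± 0.27 for rpsN (adjusted p = 2.29e-04) and 0.97 ± 0.18 for the canonical rpsR (adjusted p = 0.00886). Of the other paralogs rpmE (0.64) and MSMEG_1468 (1.63) were higher too, and the canonical rpmG (−0.02) and rpmB (−0.20) and mrf (0.87) were not called. This comparison was added after the data were seen. Ribosomes selected through the alternative S18 were drawn, in StrainB, from cells whose footprints on that gene were near the counting limit.

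**Figure D1:**
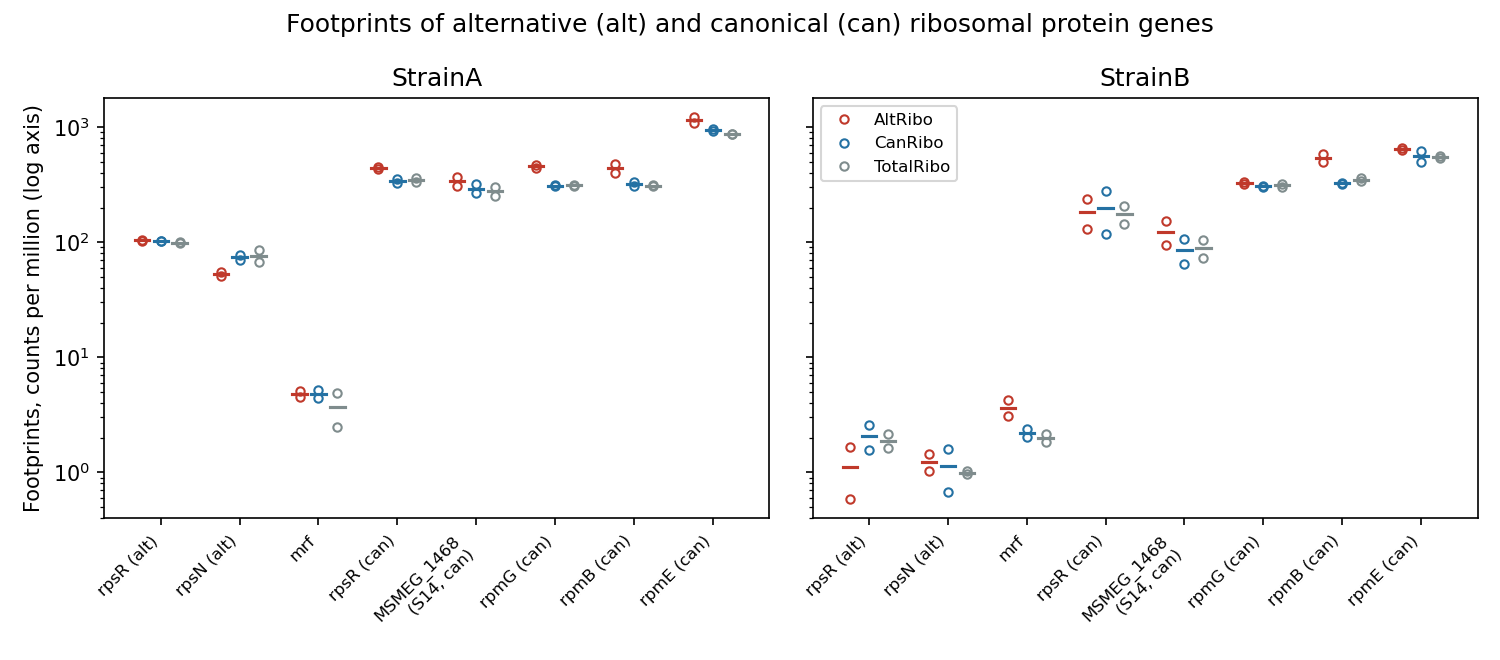
Footprints in CPM (log axis) of alternative (alt) and canonical (can) ribosomal protein genes and of mrf, in the 2 libraries (circles) and their mean (bars) of each pool, for StrainA on the left and StrainB on the right. The alternative rpsR lies near 100 CPM in StrainA, with a TotalRibo mean of 98.9, and near 2 CPM in StrainB, with a TotalRibo mean of 1.88.

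AltRibo against TotalRibo in StrainA asked which messages the selected ribosomes carried in excess of the whole ribosome population. Messages of 4 of 5 canonical zinc-binding ribosomal proteins were higher in AltRibo: rpmG (MSMEG_1339, L33) by 0.55 ± 0.08, rpmB (MSMEG_2400, L28) by 0.51 ± 0.10, rpmE (MSMEG_4951, L31) by 0.41 ± 0.09 and the canonical rpsR by 0.35 ± 0.08. The isoleucyl-tRNA synthetase gene ileS rose from 182 ± 0.197 CPM in TotalRibo to 399 ± 28.1 CPM in AltRibo (1.13 ± 0.09, adjusted p = 2.06e-05), while CanRibo held 175 ± 7.35 CPM. Most tRNA genes were lower, 40 of 46 with a median of −2.26, and all 6 rRNA genes were lower with a median of −1.93. The rRNA genes are near-identical copies, and rRNA was depleted from these libraries, so its level may also depend on that step. It took 11.6% and 7.78% of the StrainA TotalRibo libraries. Among the other genes, the called ones with the largest fold changes had no symbol in the reference table. MSMEG_1241 (2.45 ± 0.55, from 2 and 4 counts in TotalRibo), MSMEG_6048 (1.22), MSMEG_1240 (1.22) and MSMEG_0278 (1.09) were highest. MSMEG_6397 (−4.63 ± 0.61, with 2 and 8 counts in AltRibo), MSMEG_6691 (−4.07), EBG00000994450 (−4.02), MSMEG_3794 (−3.91) and MSMEG_4371 (−3.74) were lowest. Within the alternative operon, rpsN fell by 0.54 (SE 0.12, adjusted p = 0.0125), rpsR measured 0.06 ± 0.08 (adjusted p = 0.669) and mrf, which encodes a ribosome hibernation-recruiting factor, 0.37 ± 0.33. The alternative rpmB measured 1.10 ± 0.42 (adjusted p = 0.102) and the alternative rpmG 0.64 ± 0.54. In all, edgeR called 389 genes higher and 602 lower of 6058, and DESeq2 276 and 443. The authors' deposited table has 358 and 653, with 813 genes called in that table and here. With the replicate number as a block, 1098 were higher and 1166 lower, and MSMEG_1468, at the position of the canonical S14, passed too (0.29, adjusted p = 1.07e-07, against 0.121 without the block). Leaving out a TotalRibo library left 465 (replicate 1) or 556 (replicate 2) calls.

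Of all 6058 genes 16.4% were called in this comparison, and several list counts below lie near that share. Camera without the block called the canonical paralogs, the ribosomal proteins and the rRNA and tRNA genes. The other lists it tested had an adjusted p of 0.390 to 0.894. The canonical paralogs as a list of 5 had 4 higher and 0 lower (5 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 0.00856), and 56 ribosomal proteins, which include both paralog sets, had 9 higher and 2 lower (9 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.0388). With an estimated correlation between genes, the adjusted p of every planned list test, these included, was 0.996. Among ribosomal proteins rpsT rose by 0.69 and rpsE fell by 0.47. Translation factors had 3 higher, among them infA (0.47) and efp (0.38), and 1 lower of 18, the 30S maturation factor rimM at −0.50 (6 and 4 adjusted over the list alone). Nucleotide synthesis genes went both ways, with 6 higher and 4 lower of 31 (8 and 5 adjusted over the list alone): ndk (0.56) and pyrH (0.49) rose, gmk (−1.12) and pyrF (−1.07) fell. Amino acid synthesis had 2 higher and 8 lower of 58 (2 and 9 adjusted over the list alone), with aroQ at 0.58 and the glutamate synthase gene gltB (MSMEG_3225) at −0.82. Iron genes had 2 higher and 6 lower of 29 (2 and 7 adjusted over the list alone), with the bacterioferritin gene bfr at 0.34 and the mycobactin synthesis gene mbtB at −0.60. Of 39 ESX secretion genes 6 were lower and 0 higher (8 and 4 adjusted over the list alone), such as MSMEG_0063 at −0.59. Chaperones and proteases had 4 of 20 lower (also 4 adjusted over the list alone), with dnaJ (MSMEG_0711) at −0.64 and clpB at −0.39. Fatty and mycolic acid synthesis had 1 higher, hadB (0.43), and 3 lower of 14, including hadA (−0.78) and the FAS-I gene MSMEG_4757 (−0.75); 1 and 4 were called adjusted over the list alone. TCA cycle genes had 2 higher of 14, sucC (0.36) and sucD (0.35), and 2 of 8 ATP synthase genes were lower, MSMEG_4935 (−0.35) and MSMEG_4939 (−0.33), the same counts adjusted over the list alone. DosR and hypoxia genes had 2 of 14 lower, MSMEG_3930 (−0.87) and MSMEG_3931 (−0.78), 2 also adjusted over the list alone, and camera called the list down only with the block (adjusted p = 0.00431 against 0.390 without). RNA polymerase and sigma factors had rpoZ higher (0.43) and nusA lower (−0.29) of 15, with 1 and 0 adjusted over the list alone. The cytochrome list had ctaE higher of 9 (0.34) and the aminoacyl-tRNA synthetases ileS higher of 16, with 1 and 0 adjusted over either list alone. In the alternative operon 1 of 5 was lower. None of 7 zinc homeostasis genes and none of 5 NADH dehydrogenase genes was called, over all genes or adjusted over the list alone, at medians of 0.10 and −0.56. The rRNA and tRNA list had 46 of 52 lower (48 adjusted over the list alone, camera adjusted p = 5.13e-164). With the replicate block 2264 of all genes were called. More list members were called too, and several lists went both ways. Ribosomal proteins had 24 higher and 5 lower, translation factors 10 and 4, nucleotide synthesis 11 and 7, and amino acid synthesis 12 and 15. Higher and lower members numbered 4 and 9 for iron, 7 and 13 for ESX secretion, 4 and 9 for chaperones and proteases, 4 and 3 for the TCA cycle, and 3 and 3 for ATP synthase. For fatty and mycolic acid synthesis and for RNA polymerase and sigma factors they were 2 and 4 each, for aminoacyl-tRNA synthetases 5 and 1, and for cytochromes 3 and 1. DosR and hypoxia had 0 and 9, zinc homeostasis 2 and 0, NADH dehydrogenase 0 and 1, and rRNA and tRNA 2 and 48.

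In StrainB the same comparison gave no edgeR call among 5943 genes, with tRNA genes at a median of −0.61 (12 of 44 above 0) and rRNA genes at a median of 1.46. The canonical rpmB measured 0.64 ± 0.14 (542 ± 65.4 CPM in AltRibo and 350 ± 11.02 CPM in TotalRibo), rpmE 0.25 ± 0.12, rpmG 0.07 ± 0.13 and the canonical rpsR 0.08 ± 0.32. MSMEG_1468 measured 0.49 ± 0.28, mrf 0.86 ± 0.38 and the alternative rpsR −0.67 ± 0.60, the last from 16 and 4 footprints in AltRibo. Of the lists, 53 ribosomal proteins stood up (median 0.17, camera adjusted p = 0.0268) and 50 rRNA and tRNA genes down (median −0.48, camera adjusted p = 0.00268); both had an adjusted p of 0.996 with an estimated correlation. Adjusted over the list alone, 1 canonical paralog was higher, RNA polymerase and sigma factors had 2 higher and 1 lower, and rRNA and tRNA genes 6 higher and 16 lower; over all genes no list had a member called without the block. An unadjusted p below 0.05 was reached by 764 genes in edgeR, DESeq2 called 28 higher and 16 lower, and the authors' deposited table has 24 and 23. With the replicate number as a block edgeR called 713 higher and 599 lower, rpmB (adjusted p = 2.55e-05), rpmE (adjusted p = 0.0131) and MSMEG_1468 (adjusted p = 0.00105) among the higher ones, and camera the canonical paralogs (adjusted p = 0.0389 against 0.222 without the block). Ribosomal proteins then had 23 higher and 1 lower, rRNA and tRNA genes 12 and 24, ESX secretion 9 and 4, and DosR and hypoxia 6 and 3. Chaperones and proteases had 6 and 3, TCA cycle 6 and 1, RNA polymerase and sigma factors 5 and 1, and amino acid synthesis 6 and 13. Nucleotide synthesis had 2 and 5, fatty and mycolic acid synthesis 1 and 4, translation factors 3 and 4, and aminoacyl-tRNA synthetases 0 and 3. Iron had 2 and 2, ATP synthase 2 and 2, and cytochromes 1 and 1.

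With tags swapped, messages that differed the same way in both strains are not tied to a tag. AltRibo was bound to a resin and eluted in both strains, however, and CanRibo and TotalRibo were not. A change shared by the strains, here or against CanRibo, may therefore come from that handling, which was not tested. For AltRibo, no gene was called by edgeR in both strains, since StrainB had no call, and with the block 220 genes were higher in both strains, where 132.9 would be shared by independent lists (one-sided Fisher's exact test p = 2.2e-17), and 307 were lower in both, against 118.0 (p = 4.5e-76). A further 233 were called in opposite directions, against 252.1. Fisher's test takes genes as independent, which they are not, and each blocked fit leaves 1 residual degree of freedom. Its p-values therefore do not measure how repeatable the overlap is. Without rRNA and tRNA genes 219 were higher in both strains (131.5 for independent lists), 283 lower (109.6) and 223 opposite (241.5). Over 5880 genes, which are not independent replicates, the fold changes of the strains correlated at 0.276 (Pearson) and 0.224 (Spearman), and 57.4% had the same sign. The difference between strains was itself tested as an interaction. edgeR called 5 genes more positive and 53 more negative in StrainA of 6002, including 19 of 44 tRNA genes and all 6 rRNA genes. TotalRibo, the reference of both ratios, itself held more on tRNA genes in StrainA than in StrainB (median 2.17, 42 of 44 called). The tRNA difference in the ratio thus need not lie in AltRibo. Among coding genes, ileS (1.26 ± 0.16) and the initiation factor gene infA (0.95 ± 0.14) were more positive in StrainA, whereas the cell division gene ftsL (−1.06), the methionine synthase gene metH (−0.82) and the thioredoxin gene trxA (MSMEG_6934, −0.84) were more negative. These were chosen after their values were seen. An unadjusted p below 0.05 was reached by 889 genes, DESeq2 called 21 and 129, and the block 450 and 733, with rpmG passing only there (0.49, adjusted p = 6.96e-04 against 0.168). The other paralogs passed in neither fit: the canonical rpsR at 0.27, rpmE 0.17, the canonical rpmB −0.12, MSMEG_1468 −0.19, the alternative rpsR 0.72, rpsN −0.87 and mrf −0.48. Leaving out either StrainA AltRibo library, or TotalRibo replicate 2 of StrainB, left 0 calls, and leaving out rRNA and tRNA genes left 21.

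**Figure D2:**
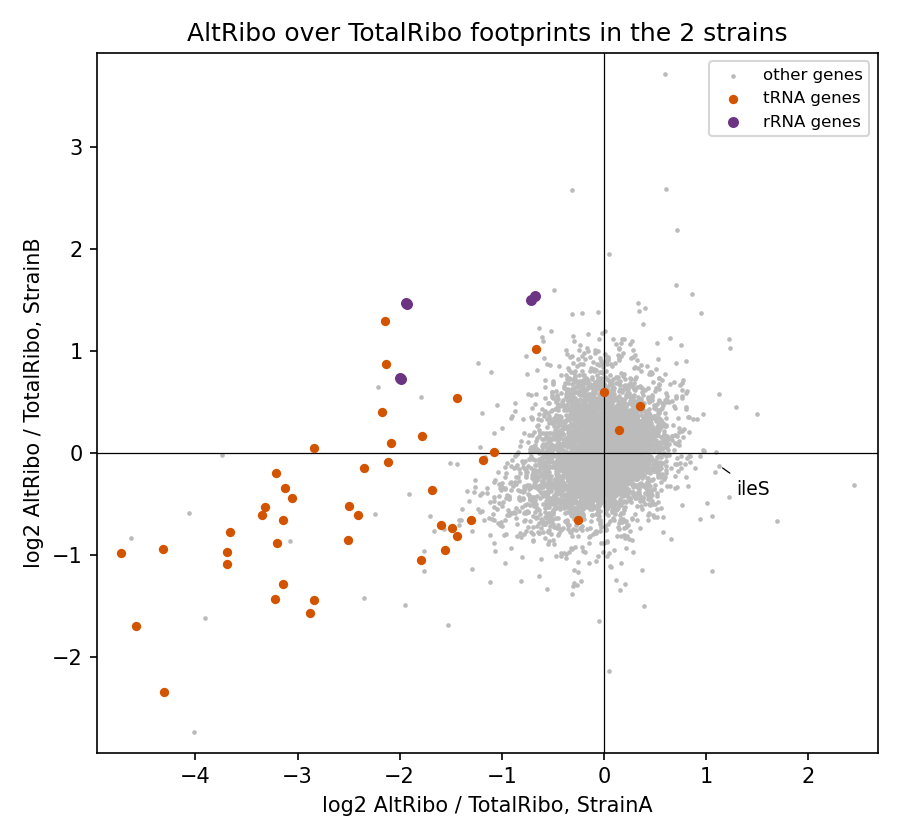
Log2 fold change of AltRibo over TotalRibo footprints per gene, StrainA on the x axis and StrainB on the y axis, with tRNA and rRNA genes coloured. The tRNA genes lie to the left (median −2.26 in StrainA, −0.61 in StrainB), the rRNA genes at the upper left (medians −1.93 and 1.46), and the genes as a whole correlate at 0.276.

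No gene was called between CanRibo and TotalRibo in either strain by edgeR. The canonical rpsR measured −0.03 ± 0.09 in StrainA and 0.17 ± 0.40 in StrainB, rpmB 0.05 ± 0.08 and −0.11 ± 0.12, and the alternative rpsR 0.04 ± 0.09 and 0.15 ± 0.47, each with an edgeR adjusted p of 1.00. Of the other paralogs, the canonical rpmG measured −0.01 and −0.03, rpmE 0.12 and 0.01, MSMEG_1468 0.08 and −0.05 and mrf 0.34 and 0.15, and rpsN −0.05 and the alternative rpmB −0.03 in StrainA. The tRNA genes lay at medians of −0.11 in StrainA (13 of 46 above 0) and 0.10 in StrainB. edgeR called 0 of 5934 genes in StrainA and 0 of 5819 in StrainB, with 79 and 47 at an unadjusted p below 0.05. DESeq2 and the authors' deposited tables called 0 in both, and the block 2 and 3. As a list, rRNA and tRNA genes were down in StrainA (camera adjusted p = 0.00277) and up in StrainB (camera adjusted p = 0.00381), neither with an estimated correlation (adjusted p = 0.996), and adjusted over the list alone 1 was lower in StrainA. Ribosomal proteins passed in StrainA only with the block (median 0.04, adjusted p = 0.0099 against 0.0859). With the block 1 rRNA or tRNA gene was lower in StrainA and 3 were higher in StrainB. No other list had a called member or a camera call, with or without the block. Fold changes of the strains correlated at 0.010 over genes, no call was shared, and the interaction gave 0 calls of 5890 in edgeR (72 at an unadjusted p below 0.05), 0 in DESeq2 and 0 with the block. Of simulated 1.5-fold changes 0% were recovered in StrainB and 55.2% in StrainA, and with the block 47.8% and 73.1%. At 2-fold these were 28.4% and 86.6%, and with the block 76.1% and 86.6%.

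**Figure D3:**
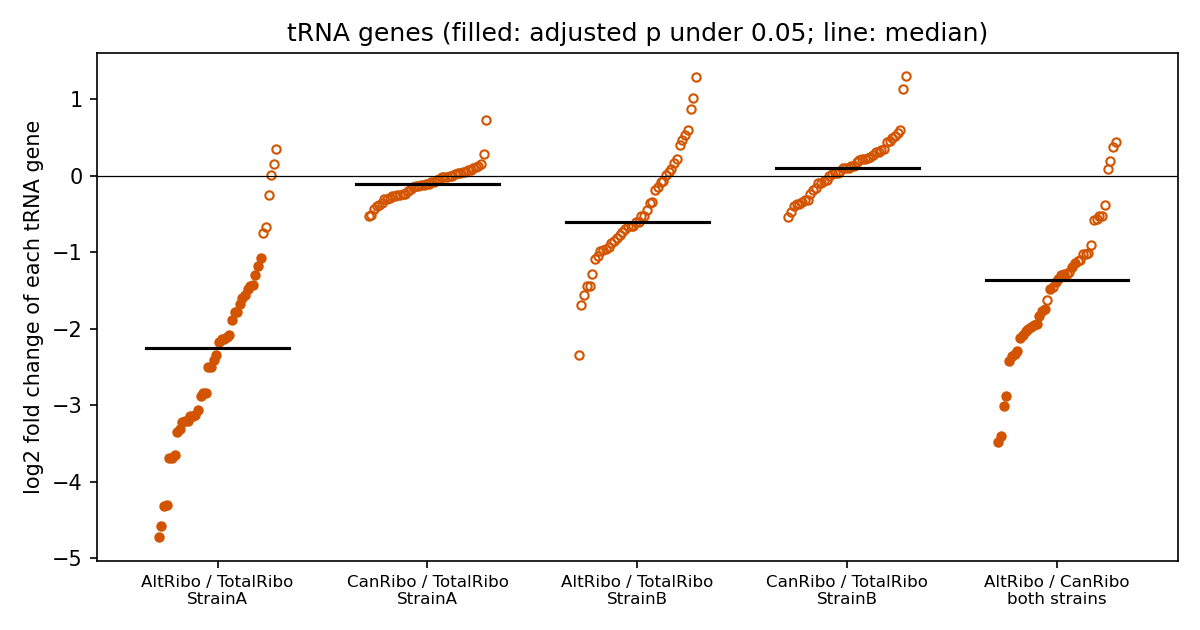
Log2 fold change of each tRNA gene, sorted within 5 comparisons on the x axis; filled circles have an edgeR adjusted p below 0.05 and lines mark medians. Medians are −2.26 and −0.61 for AltRibo over TotalRibo in StrainA and StrainB, −0.11 and 0.10 for CanRibo over TotalRibo, and −1.37 for AltRibo over CanRibo.

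Set directly against CanRibo over both strains, AltRibo held more footprints on rpmB, the canonical L28 gene (0.61 ± 0.11, adjusted p = 0.0155; 0.45 in StrainA and 0.75 in StrainB), on MSMEG_5483, 1 of several loci with the porin symbol mspA (0.52 ± 0.08, adjusted p = 0.0091; 0.48 and 0.56), on yajC, a subunit gene of the protein translocase (0.61 ± 0.10; 0.70 and 0.50), and on aroQ of the shikimate pathway (0.56 ± 0.09). It held fewer on rnpA, which encodes the protein part of ribonuclease P, at −1.19 ± 0.13 (adjusted p = 0.0074; −1.25 in StrainA and −1.13 in StrainB). In StrainA rnpA stood at 34.6 ± 1.20 CPM in AltRibo and 82.7 ± 6.33 CPM in CanRibo (SD, n = 2), and in StrainB at 43.3 ± 2.56 and 96.2 ± 27.9 CPM. Of 44 tRNA genes 24 were lower (median −1.37) and none of the 6 rRNA genes was called (median −0.38). That rRNA median joins strains whose AltRibo medians against TotalRibo had opposite signs, −1.93 in StrainA and 1.46 in StrainB. The remaining genes with the smallest p were, among the higher, MSMEG_3329 (0.69), MSMEG_5155 (0.65), MSMEG_0360 (0.60), MSMEG_1725 (0.60), MSMEG_4919 (0.60), MSMEG_1863 (0.58) and mtf2 (0.54), and, among the lower, EBG00000994450 (−2.96), MSMEG_5517 (−1.19), MSMEG_3905 (−1.18), MSMEG_0315 (−1.03), MSMEG_1822 (−0.81), MSMEG_5302 (−0.80), MSMEG_6557 (−0.70), MSMEG_3148 (−0.65) and MSMEG_6190 (−0.63). Of the other paralogs, rpmG measured 0.34 ± 0.11 (adjusted p = 0.102), rpmE 0.27 ± 0.10, the canonical rpsR 0.16 ± 0.26, the alternative rpsR −0.09 ± 0.19, rpsN −0.40 ± 0.16 and mrf 0.28 ± 0.22, none past the test, and MSMEG_1468 passed only with the block (0.38, adjusted p = 0.0346 against 0.258). edgeR called 104 genes higher and 293 lower of 5911, and all 397 had the same direction in both strains fitted alone, an agreement that choosing genes by a fit over both strains favours. Over all 5870 genes 58.5% had the same direction. DESeq2 called 179 and 414, and the block 230 and 380, of which 382 calls were shared with the fit without it. StrainA alone gave 1140 calls and StrainB alone 0, and with the block StrainA alone gave 1169 higher and 1276 lower and StrainB alone 866 and 748. The per-strain fold changes correlated at 0.312 over genes, and leaving out a library left between 75 (StrainA AltRibo replicate 1) and 432 calls.

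By list, the canonical paralogs had 1 of 5 higher in AltRibo than in CanRibo (3 adjusted over the list alone, median 0.34, camera adjusted p = 0.0388) and 54 ribosomal proteins 4 higher and 0 lower, the same adjusted over the list alone (median 0.13, camera adjusted p = 0.0406), with rplS (0.50) beside rpmB; the adjusted p of both was 0.996 with an estimated correlation. Camera called no list but these and the rRNA and tRNA genes, and of all genes 6.72% were called. Nucleotide synthesis had ndk higher (0.48) and gmk (−0.85) and pyrF (−0.93) lower of 31, as also adjusted over the list alone. Amino acid synthesis had aroQ higher and 3 lower of 57, among them both serB copies (−0.65 and −0.58), which may share reads, and 5 were lower adjusted over the list alone. Single members were called in zinc homeostasis (aztD, 0.66, of 7; 1 higher and 1 lower adjusted over the list alone), ATP synthase (MSMEG_4939, −0.48, of 8), DosR and hypoxia (MSMEG_3931, −0.59, of 14) and fatty and mycolic acid synthesis (hadA, −0.62, of 14), in these last 3 also adjusted over the list alone. No member was called without the block, over all genes or adjusted over the list alone, among translation factors, aminoacyl-tRNA synthetases, cytochromes, iron, ESX secretion, TCA cycle, chaperones and proteases, RNA polymerase and sigma factors, NADH dehydrogenase and the alternative operon. The rRNA and tRNA list had 24 of 50 lower (35 adjusted over the list alone, median −1.28, camera adjusted p = 4.77e-24), with an adjusted p of 0.996 with an estimated correlation. With the block iron genes had 1 higher and 5 lower, ESX secretion 0 and 2, RNA polymerase and sigma factors 2 and 0, translation factors 0 and 1, and chaperones and proteases 0 and 1. Amino acid synthesis had 1 and 5, DosR and hypoxia 0 and 2, ribosomal proteins 6 and 0, the canonical paralogs 2 and 0, and rRNA and tRNA genes 0 and 22.

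**Figure D4:**
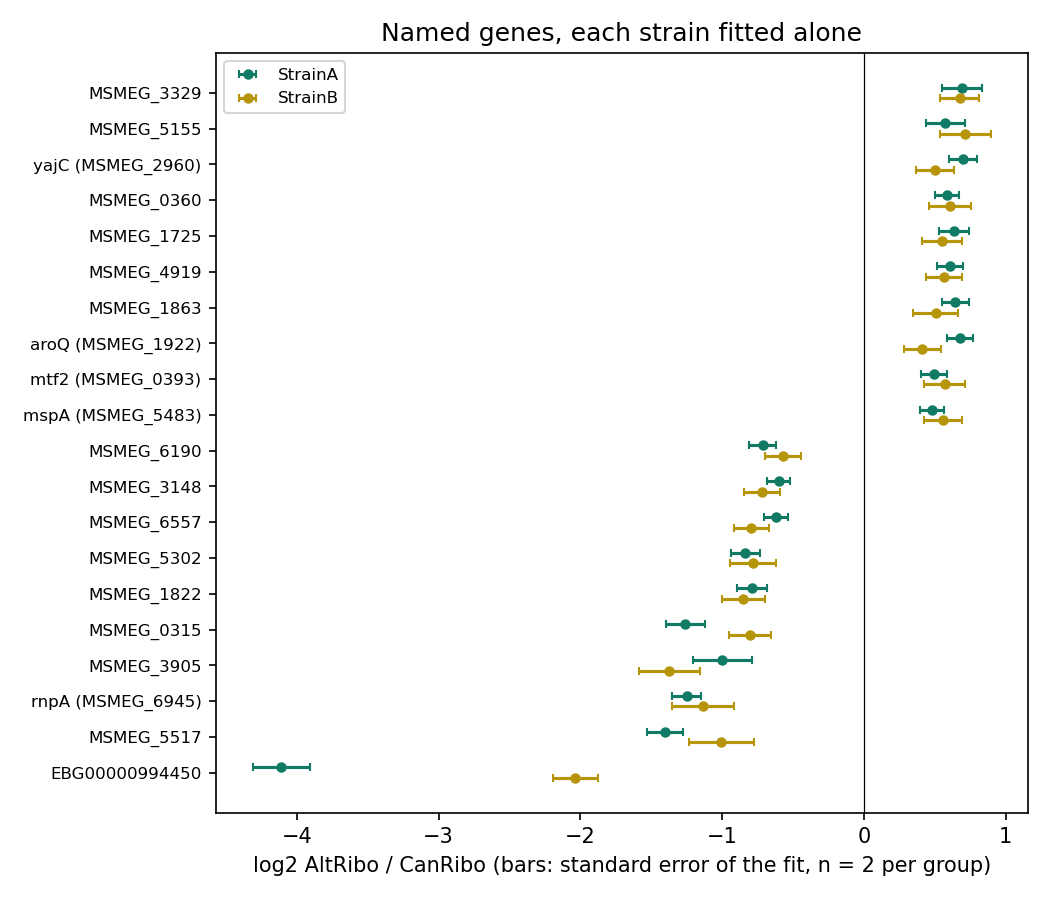
Log2 fold change of AltRibo over CanRibo for the 20 genes with the smallest p, each strain fitted alone (bars: standard error of the fit, n = 2 libraries per group). Both strains lie on the same side of 0 for each gene, which the choice by a fit over both strains favours (58.5% of all 5870 genes agree in direction), from EBG00000994450 at −4.11 in StrainA and −2.04 in StrainB to rnpA at −1.25 and −1.13 and MSMEG_5483 (mspA) at 0.48 and 0.56.

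Translation efficiency, the footprint level of a gene over its mRNA level, was compared between strains from the authors' deposited values, which have no replicates and so no test. The genes called highest and lowest here and in the next paragraph are those among 2931 above the median footprint level, and genes below it can lie further out. In AltRibo the gene arsC (1.72), named for arsenate reductase, and MSMEG_6456 (2.20), MSMEG_1251 (2.01), MSMEG_0557 (1.85) and MSMEG_1788 (1.76) had the highest log2 ratios of StrainA to StrainB, and MSMEG_0493 (−2.39), MSMEG_5542 (−2.03), MSMEG_1193 (−1.43), MSMEG_6172 (−1.40) and MSMEG_5816 (−1.32) the lowest. In CanRibo hadA, a dehydratase gene of mycolic acid synthesis (1.55), MSMEG_1317 (1.63), MSMEG_0557 (1.501), MSMEG_6223 (1.45) and MSMEG_6227 (1.42) were highest and MSMEG_5542 (−1.55), MSMEG_5816 (−1.33), MSMEG_2626 (−1.32), MSMEG_6190 (−1.28) and MSMEG_5011 (−1.28) lowest. In TotalRibo MSMEG_1251 (1.68), MSMEG_1317 (1.58), MSMEG_6227 (1.45), MSMEG_0557 (1.38) and MSMEG_0538 (1.36) were highest, and MSMEG_2626 (−1.56), MSMEG_5517 (−1.41), rimM (−1.38), MSMEG_5542 (−1.38) and rnpA (−1.36) lowest. From the fixed list, the alternative rpsR stood at −1.83, −3.06 and −3.02 in AltRibo, CanRibo and TotalRibo and rpsN at −2.78, −2.48 and −2.31, with StrainB values that rest on few footprints. The canonical rpsR stood at 1.67, 1.02 and 1.23 and MSMEG_1468 at 1.19, 1.24 and 1.01, and the others of that list between −0.81 and 0.47. The strains were more than 2-fold apart for 732 of 6414 genes in AltRibo (604 higher in StrainA), 517 of 6392 in CanRibo (319 higher) and 493 of 6389 in TotalRibo (290 higher), at median log2 ratios of 0.25, −0.09 and −0.14. Among genes of at least 5 log2 CPM, 81 were higher and 24 lower in AltRibo, but 15 and 21 in CanRibo and 13 and 22 in TotalRibo. Centred on the median, 365 were higher and 256 lower in AltRibo, 347 and 153 in CanRibo and 372 and 138 in TotalRibo. Log2 TE correlated between strains at 0.827, 0.817 and 0.793 across genes. A TE of 0 in a strain was listed for 27, 49 and 52 genes.

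Within a strain, mRNA abundance cancels in the ratio of AltRibo TE to CanRibo TE. Among the genes above the median footprint level, the highest ratios in both strains were those of MSMEG_5484 (0.77 in StrainA and 0.71 in StrainB), MSMEG_0557 (0.69 and 0.67), mrx1, a mycoredoxin gene (0.71 and 0.64), MSMEG_5170 (0.67 and 0.63) and sp36 (0.73 and 0.61). Lowest were rnpA (−1.17 and −1.10), MSMEG_5517 (−1.42 and −1.01), MSMEG_4284 (−1.25 and −0.89), MSMEG_3790 (−0.99 and −0.85) and MSMEG_2626 (−0.83 and −1.21). The canonical rpmB stood at 0.39 and 0.56, MSMEG_1468 at 0.23 and 0.61 and rpmE at 0.12 and 0.21, whereas the canonical rpmG (0.48 and −0.05) and rpsR (0.32 and −0.0049) did not agree between strains. In the alternative operon rpmB stood at 1.14 and 0.19, rpsN at −0.48 and 0.15, rpsR at 0.03 and −0.87 and mrf at −0.03 and 0.88. Over 6387 genes 57.7% had the same direction in both strains (95% exact binomial interval 56.5% to 58.9%, for counting error only). The ratios correlated at 0.170, and 12 genes of any footprint level were above and 37 below 2-fold in both. Without centring, the share with the same direction was 50.8%.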

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

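The tests of what stays in the flow-through, of the replicate block, of amplification around the tagged locus and of zinc limitation were chosen after the results they bear on had been seen. A test of the difference between strains in the ratio of AltRibo to TotalRibo marked 58 genes, among them 19 tRNA genes and all 6 rRNA genes. The TotalRibo reference itself was higher on tRNA genes in StrainA than in StrainB, at a median of 2.17. The rRNA genes are near-identical copies, and their level may depend on the depletion of rRNA, which was not tested. The test of the strain difference marked ileS at 1.26 (1.13 in StrainA and −0.12 in StrainB) and infA at 0.95 (0.47 and −0.47), both more positive in StrainA. MSMEG_4371 stood at −3.71 (−3.74 in StrainA and −0.02 in StrainB), from 9 and 25 AltRibo counts in StrainA. Groups of 2 libraries allow no search for outlying samples.

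Genes for tRNA were lower in AltRibo than in TotalRibo in StrainA, with 40 of 46 called and a median of −2.26. In StrainB the median was −0.61 over 44 genes, 12 of them above 0. Of all genes edgeR called none without the block, although 764 had an unadjusted p below 0.05, and DESeq2 called 44 of all genes. Adjusted over the list alone, 16 rRNA and tRNA genes were lower and 6 higher, and with the block 24 were lower and 12 higher. All 6 rRNA genes lay above 0 in the fit without the block. In edgeR a decrease there is thus shown gene by gene only over the list alone or with the block, and for part of the tRNA genes. With the StrainA libraries thinned to the smallest total the median was −2.37. Thinning keeps the expected share of each gene in its library, so this cannot decide whether library depth plays a part. An open explanation is that tRNA not held by selected ribosomes is washed off the resin and stays in the other pools, and the StrainA data are consistent with it, since CanRibo, the flow-through, lay at −0.11 against TotalRibo (0.10 in StrainB). A difference in tRNA bound to AltRibo itself stays open and untested, as the lysate and the eluted pool also differ in handling.

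AltRibo fold changes differed between the strains. Their reference, TotalRibo, differed too, with 865 genes higher and 743 lower in StrainA of 5871, so the difference need not lie in AltRibo. StrainA libraries thinned to the StrainB totals still gave 687 calls, so lower depth alone would not remove the StrainA calls. Thinning keeps the expected fold changes, so it cannot decide whether depth plays a part in how they differ between strains. Replicate noise is argued against as the whole cause, because ratios made from separate libraries correlated at 0.704 within StrainA and 0.429 within StrainB, but only at 0.208 to 0.223 between strains (a smallest gap of 0.206). Spread shared by same-numbered StrainB libraries may account for the lack of StrainB calls, since the block brought 1312. Tag, resin and strain change together in this design, and so does the level of the alternative rpsR, so these stay open and untested as sources of the difference.

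Footprints on the alternative rpsR and rpsN were higher in StrainA than in StrainB in TotalRibo, by 5.68 and 6.21. Amplification of the whole surrounding region is argued against by the 20 nearest measured genes outside the operon. They had a median absolute difference of 0.522, at the 86.7th percentile of 10000 random places on the chromosome. MSMEG_6064, the locus numbered next to the alternative rpsR, was higher in StrainA by 1.91 (edgeR adjusted p = 0.00127). A median over 20 genes cannot decide on an amplification limited to the operon and its nearest gene. Zinc limitation of StrainA was looked for in the 7 zinc homeostasis genes, which lay at a median of −0.44 (SD 0.637, highest 0.96). Of these 2 lay above 0 and none was called. The list holds few known members of that response, and they need not all move the same way. This median therefore cannot decide on zinc limitation. The deposited TE of the alternative rpsR was lower in StrainA (−3.02), which puts the implied mRNA difference at 8.69. A local effect of the tag within the operon, or another change in StrainB, stays open and was not tested.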

How the results depend on the processing

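Alternatives chosen after the data were seen were, for AltRibo against CanRibo and the strain differences, DESeq2, the stricter thresholds and the removal of rRNA and tRNA genes, as well as the block in the strain differences and gene lists, the thinned libraries and every setting of the TotalRibo comparison. Each setting below moved a count by more than 1.5 times, or a share out of its 95% interval; where the setting does not itself say why (fewer samples, genes or a stricter threshold), the cause was not tested. The replicate block gave 2264 calls for AltRibo against TotalRibo in StrainA, 1312 in StrainB, 527 shared by the strains and 1183 for the strain difference, 2 and 3 for CanRibo in StrainA and StrainB, and 610 for AltRibo against CanRibo; it changed no call of a named gene or list other than those given beside the results. DESeq2 gave 44 calls for AltRibo in StrainB and 150 for the strain difference. An FDR of 0.01 left 373 (AltRibo, StrainA), 70 (AltRibo against CanRibo), 0 (strain difference) and 625 (TotalRibo between strains), and an absolute log2 fold change of at least 1 left 115, 54 and 661 of the first, second and last of these. The strain difference fell to 21 calls without rRNA and tRNA genes and rose to 92 among genes of at least 5 log2 CPM. AltRibo against CanRibo gave 1140 calls in StrainA alone and 0 in StrainB alone, and with the block 1169 higher and 1276 lower in StrainA alone and 866 and 748 in StrainB alone. Camera with an estimated correlation and fry each called 0 planned lists, against 10 with the preset value. Among genes of at least 5 log2 CPM, 105, 36 and 35 genes were more than 2-fold apart in TE (AltRibo, CanRibo, TotalRibo), and the share of genes with the same direction of AltRibo to CanRibo TE was 59.0%, against 50.8% as deposited. Another scaling, no filter, pseudocounts of 0.1 and 0.01 and centring of the strain ratios left each total count within 1.5 times. The thinned StrainA libraries did too (687). The split of the AltRibo TE count moved by more, from 604 higher and 128 lower in StrainA to 365 and 256 with centring. With a pseudocount of 0.1 it was 463 and 84. CanRibo between strains had 0 calls in all settings. Of simulated 1.5-fold changes in StrainB, 4.48% (AltRibo) and 0% (CanRibo) were recovered, and 68.7% and 47.8% with the block at the same library sizes. Each simulation took its dispersion from its own design, so the higher recovery with the block reflects that input. It cannot decide what part depth plays in these limits.

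Leaving out 1 library, its lone partner being assumed to vary like the other groups, gave 465 to 954 calls for AltRibo in StrainA (465 and 556 without TotalRibo replicate 1 or 2), 0 to 1 in StrainB (1 without either AltRibo library), 0 to 17 for CanRibo in StrainA (7 and 17 without TotalRibo replicate 1 or 2, 2 without CanRibo replicate 2), and 472 to 2322 for TotalRibo between strains (472 and 567 without TotalRibo replicate 1 or 2 of StrainA). AltRibo against CanRibo ranged from 75 to 432 (75 and 104 without StrainA AltRibo replicate 1 or 2, 111 and 106 without StrainA CanRibo replicate 1 or 2, 236 without StrainB AltRibo replicate 2, 219 without StrainB CanRibo replicate 1). The AltRibo strain difference ranged from 0 to 78 (0 without either StrainA AltRibo library or StrainB TotalRibo replicate 2, 3 without StrainB TotalRibo replicate 1, 10 and 24 without StrainA TotalRibo replicate 1 or 2). Of 138 values of named genes, 84 were called. The 1614 recomputed values kept direction and side of the threshold in 1411 cases and lost the call in 147 (106 of them with a library left out). They gained it in 12 and changed sign in 44, with no value called in the main fit among the last.

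Sign changes were in values not called in the main fit, although some of these genes were called in other comparisons. They were 25 values with a library left out and 2 otherwise: the alternative rpsR (MSMEG_6065) at 0.017 for AltRibo against CanRibo in StrainA alone and the canonical rpsR (MSMEG_6895) at −0.087 in StrainB alone. With a library left out, the AltRibo fold change of mrf in StrainA ranged from −0.031 to 0.96 and that of the canonical rpsR in StrainB from −0.40 to 0.46. CanRibo in StrainA ranged from −0.21 to 0.13 for rpsN, −0.25 to 0.16 for the alternative rpmB, −0.055 to 0.94 for mrf, −0.10 to 0.034 for the canonical rpsR, −0.034 to 0.011 for rpmG and −0.063 to 0.22 for MSMEG_1468. CanRibo in StrainB ranged from −0.24 to 0.43 for the alternative rpsR, −0.53 to 0.64 for the canonical rpsR, −0.099 to 0.036 for rpmG, −0.14 to 0.15 for rpmE and −0.42 to 0.25 for MSMEG_1468. The AltRibo strain difference ranged from −0.88 to 0.11 for mrf, −0.095 to 0.77 for the canonical rpsR, −0.27 to 0.013 for rpmB and −0.48 to 0.19 for MSMEG_1468. The CanRibo strain difference ranged from −0.39 to 0.29 for the alternative rpsR, −0.69 to 0.49 for rpsN, −0.21 to 0.81 for mrf, −0.68 to 0.51 for the canonical rpsR, −0.046 to 0.090 for rpmG, −0.026 to 0.27 for rpmE and −0.17 to 0.51 for MSMEG_1468. TotalRibo between strains ranged from −0.087 to 0.048 for rpmG. The cause was not tested.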

Other observations

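The comparison of TotalRibo between strains was chosen after the data were seen. Footprints on ribosomal protein genes were higher in StrainA than in StrainB, with 38 of 54 higher and 1 lower (median 0.89), for example rpmJ (1.18 ± 0.13), while rplI, next to the canonical rpsR, was the 1 lower at −2.06 ± 0.13. Siderophore and iron uptake genes followed, with 13 of 29 higher and 0 lower (median 0.87), among them mbtB (2.22 ± 0.39) and mbtI (1.37 ± 0.26) of mycobactin synthesis. ATP synthase went the other way, with 7 of 8 lower (median −0.98), such as MSMEG_4939 (−1.76 ± 0.16) and atpB (−1.36 ± 0.13). Chaperones and proteases had 8 of 20 lower and 0 higher (median −0.45), including groL (MSMEG_1978, −1.14) and grpE (−1.70). With camera the adjusted p was 2.37e-14 for ribosomal proteins, 3.48e-04 for iron, 1.72e-07 for ATP synthase, 0.007 for chaperones and 2.38e-44 for rRNA and tRNA genes (44 of 50 higher, median 2.13). With an estimated correlation the adjusted p was 0.641 for ribosomal proteins, iron and chaperones and 0.561 for ATP synthase, so none of the 5 calls held.

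Single members of other lists were called too, but these lists did not pass camera (adjusted p of 0.0531 for fatty and mycolic acid synthesis to 0.842 for cytochromes), and 27.4% of all genes were called. Fatty and mycolic acid synthesis had 5 of 14 higher in StrainA, with acpM (1.54), kasB (1.59) and hadA (1.55), and 1 lower, the cyclopropane synthase gene pcaA (−0.85). Of 14 DosR and hypoxia genes 4 were lower, among them MSMEG_3927 (−0.95) and MSMEG_3928 (−0.89). The stress sigma factor gene sigH (1.28) and rbpA (0.59) were the 2 called of 15 transcription genes. ESX secretion had 8 higher, such as espB (0.95), and 4 lower, such as eccE (MSMEG_0082, −0.71), of 39. The elongation factor genes tuf (0.72) and tsf (0.49) were higher, and of 9 cytochrome genes qcrB (−0.55) and ctaD (MSMEG_4437, −0.65) were lower and MSMEG_3233 (0.50) higher. Among 44 tRNA genes 42 were higher (median 2.17). edgeR called 865 genes higher and 743 lower of 5871, and DESeq2 742 and 499. Strain, culture and any shared day of the libraries cannot be separated in this comparison, and leaving out TotalRibo replicate 1 of StrainA left 472 calls.

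Other splits of the libraries were set beside the direct comparison of AltRibo with CanRibo. Because replicate numbers were taken to pair the libraries, only the 8 splits that part every pair compare with the real one, too few for a share under 0.05. The real split gave 397 calls and the highest of the others 2, that of StrainA AltRibo with StrainB CanRibo against the remainder. The others differ from the real split in that they exchange the pools within some pairs. A difference between pools then adds to their residual spread, so low counts are favoured by how these splits are made. They are no test of the 397 calls. With the block the real split gave 610 calls and the others 0 each.

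Neighbouring genes tended to share their AltRibo to CanRibo change. The log2 fold changes of 5178 pairs of adjacent genes correlated at 0.0565, above the highest of 10000 random gene orders (0.0509), so a part of the change may be set per transcript, though a small one. Overlapping reads at gene borders would act the same way and were not tested.

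Change in AltRibo also followed translation efficiency. Across genes, which are not independent replicates, the log2 ratio of AltRibo to CanRibo correlated with the TotalRibo TE, which shares no footprint library with it, at a Spearman coefficient of 0.142 over 5843 genes in StrainA and 0.339 over 5765 in StrainB. A hypothesis is that genes with few ribosomes per mRNA are lower in AltRibo. It would not cover rnpA, whose TotalRibo TE of 1.19 in StrainA and 3.05 in StrainB lay above the medians of all genes (0.883 and 0.932). RNA fragments not held by ribosomes could produce the relation too and were not tested.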
